A study of Mus musculus with 9 samples.

How the data were processed

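Gene expression was measured on 9 one-colour (Cy3) Agilent mouse arrays, 1 per clone of p53-deficient mouse embryonic cells: 3 diploid, 3 triploid and 3 tetraploid clones. Per the labels, the cells were grown in serum-supplemented medium without treatment, and RNA was purified on columns and labelled with the Quick Amp kit. The genotype field names p53 for all 9 clones; the free-text descriptions of all but diploid clone 1 give rising numbers in its place, read here as an error of entry. Per the file headers, the spots were read with Feature Extraction 10.7.3.1 and the design of the array was drawn up on the mouse genome build mm9.

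The deposited scanner files give, per spot, the processed signal in intensity units, after background subtraction and detrending by the scanner software and with no normalization between arrays. The authors also deposited a table of log2 values, in which diploid clone 1 was, per the labels, the reference. Checked against the scanner files, its values equalled the log2 processed signal minus a constant per array and minus the value of diploid clone 1, within 0.001 at 100% of probes. Its values for diploid clone 1 are thus 0 at every probe. Taking the same value per probe from all arrays leaves differences between groups unchanged, so the table departs from the scanner values only by the constant per array. The scanner files were used for the main tests, and the table served as an alternative. The files give spots no gene names and no mean pixel signal, so the planned normexp background correction ran on median pixel signals instead.

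The 59305 spots that are not controls held 55681 different probes. Probes on several spots were averaged on the log2 scale, and each array was centred on its 75th percentile, so that a value of 0 is that percentile. A probe was kept when the software called it well above background on all arrays of at least 1 group. Of the probes, 25469 were kept, and 83 were dropped because the software had marked all their spots on an array as not uniform or as outliers. RefSeq accessions of the array design were paired with symbols through a table of the assembly GRCm38.p6, used for names and for the chromosome of each gene; no coordinates of that table were printed. Of the 55681 probes, 26413 had a symbol and 29268 did not. Where several kept probes measured a named gene, as for 3092 genes, the brightest on average over all arrays stood for it. Tests ran over 21797 features, 12434 named genes and 9363 probes without a name.

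Between 44.8% and 50.9% of spots per array lay well above background, and 0 were saturated. The 75th percentile of the processed signal lay between 215 and 407. Arrays give no counts, so the number of clones limits the precision. Fold changes of a gene that was dark on all 3 arrays of a group were computed against the lowest signal called well above background on those arrays and are given as "at least"; the fitted log2 differences of such genes are no bounds. For genes dark on part of a group's arrays, the difference of means with those arrays at the same lowest signal is given too for the larger differences.

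The comparisons were triploid against diploid, tetraploid against diploid, triploid against tetraploid, triploid against the mean of the other groups, and any difference among the 3 groups. Linear models with 1 mean per group were fitted with limma 3.58.1 in R 4.3.3, with moderated statistics (prior degrees of freedom 3.19) and Benjamini-Hochberg adjustment over all features. The threshold was an adjusted p of 0.05. Differences are log2 differences ± standard error (SE) of the model, and levels are means ± standard deviation (SD) over 3 clones. Nothing in the labels says that the clones of a group came from separate cultures or animals. The sample names of 7 clones extend that of diploid clone 1, and diploid clone 2 has a name of its own, and whether clones descend from a common line is not stated. P-values thus measure only the spread between these samples.

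Gene lists were fixed before the data were examined. Of 45 lists, 44 had at least 5 measured members and were tested with camera at a preset correlation of 0.01 between genes; camera with an estimated correlation and fry were run beside it. Chromosomes were compared through the median, per array, over the named genes of each chromosome after centring each gene on its mean, tested with limma over 20 chromosomes. For single clones, each chromosome's median difference from the mean of the diploid clones, after centring the clone on its median over all genes, was set against 10000 random gene sets of the same size, drawn with replacement from genes in the same 20 bins of mean signal. For a diploid clone, the reference was the mean of the other 2. Spread within groups was compared by exact permutation tests.

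Named genes followed a rule written before the data were examined: per pair of groups the 10 largest differences in each direction among called genes whose groups did not overlap (5 for the comparison with the mean of the other groups), or the 5 of smallest p as values only where none was called. For each list up to 4 called members were added, smallest p first, or else 2 as values only, and Trp53, Xist, Ddx3y, Eif2s3y, Kdm5d and Uty in all cases.

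On simulated data with the size and spread of triploid against diploid (21797 features), the procedure recovered 5 of 50 genes changed by a log2 difference of 1, 35 of 50 changed by 2, 48 of 50 changed by 4 and 49 of 50 changed by 6, and called 13 of 21597 unchanged genes.

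Alternatives fixed beforehand were quantile normalization, normexp background correction, other filters on dim probes, slide as a fixed or random block, clone number as a block, fits on 2 groups alone, trended robust moderation, array weights, means over probes or chromosomes, the deposited log2 table, and each clone left out in turn. Scaling to the 75th percentile of probes well above background on all 9 arrays, centring on the median of tested genes, chromosome medians relative to all genes placed on chromosomes, and tests of named genes alone were chosen after seeing the data. Diploid clone 1 was alone on 1 slide and the other 8 clones shared another, so a fixed slide block equals leaving out diploid clone 1. Whether clone numbers pair the arrays was not settled. Residuals of the 9 pairs of like number correlated at -0.13 to 0.09, 0 of them above 0.1, and those of unlike number at -0.07 to 0.13. The best match among the 3 clones of another group had the same number in 11 of 18 tests. Results on some single genes are not reported here. Files were read with the R packages data.table, version 1.17.8, and jsonlite, version 2.0.0.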

Results

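The series compared gene expression between clones of mouse embryonic cells that lack the tumour suppressor p53 and differ in ploidy, the number of chromosome sets. Its title places triploidy in the context of genome instability and tumour formation. The 9 arrays covered 3 diploid, 3 triploid and 3 tetraploid clones, 1 array per clone. The share of spots well above background was 48.0%, 48.0% and 50.4% for diploid clones 1 to 3, 47.9%, 50.8% and 47.5% for the triploid clones and 46.2%, 44.8% and 50.9% for the tetraploid clones. Across genes, which are not independent replicates, diploid clones correlated with each other at Pearson's r of 0.969 to 0.981. Triploid clones 2 and 3 reached 0.985, and triploid clone 1 stood apart from them at 0.948 and 0.956. Tetraploid clones correlated at 0.955 to 0.978. Values between groups ran from 0.909 to 0.975 and overlapped those within groups: tetraploid clone 1 reached 0.975 with diploid clones 1 and 3, and triploid clone 1 reached 0.964 with diploid clone 2, above its values with the other triploid clones. The first principal component held 41.7% of the variance and the second 18.6%.

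The probe for Trp53, the gene of p53, lay well above background on 1 of 9 arrays, diploid clone 2, at a log2 value of -3.15 relative to the 75th percentile of the array. The other 8 values lay between -3.30 and -6.63. The genotype label was the same for all 9 clones. The labels do not state whether the probe lies in the deleted part of the gene, so its level does not check the genotype.

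The sex-linked genes separated the clones within and between groups. Ddx3y, a Y-linked RNA helicase, had log2 values of 1.32, 0.63 and 1.79 in diploid clones 1 to 3 and of 2.01 and 2.51 in tetraploid clones 1 and 2. Eif2s3y, a Y-linked translation factor, was bright in the same 5 clones. Both were dark in all 3 triploid clones and in tetraploid clone 3. Triploid clones were at least 31.3-fold lower than diploid clones for Ddx3y and at least 77.7-fold lower for Eif2s3y. Neither difference passed the test (adjusted p = 0.0975 and 0.0821, limma), and both passed without tetraploid clone 3 (adjusted p = 0.000117 and 0.000142). Xist, the RNA that silences an X chromosome, was above background at both of its probes in diploid clones 1 and 2, triploid clones 1 and 2 and tetraploid clone 3. Of the other Y-linked genes, Kdm5d was dark on all arrays and Uty lay above background at 1 of its 2 probes in diploid clone 3 alone.

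**Figure D1:**
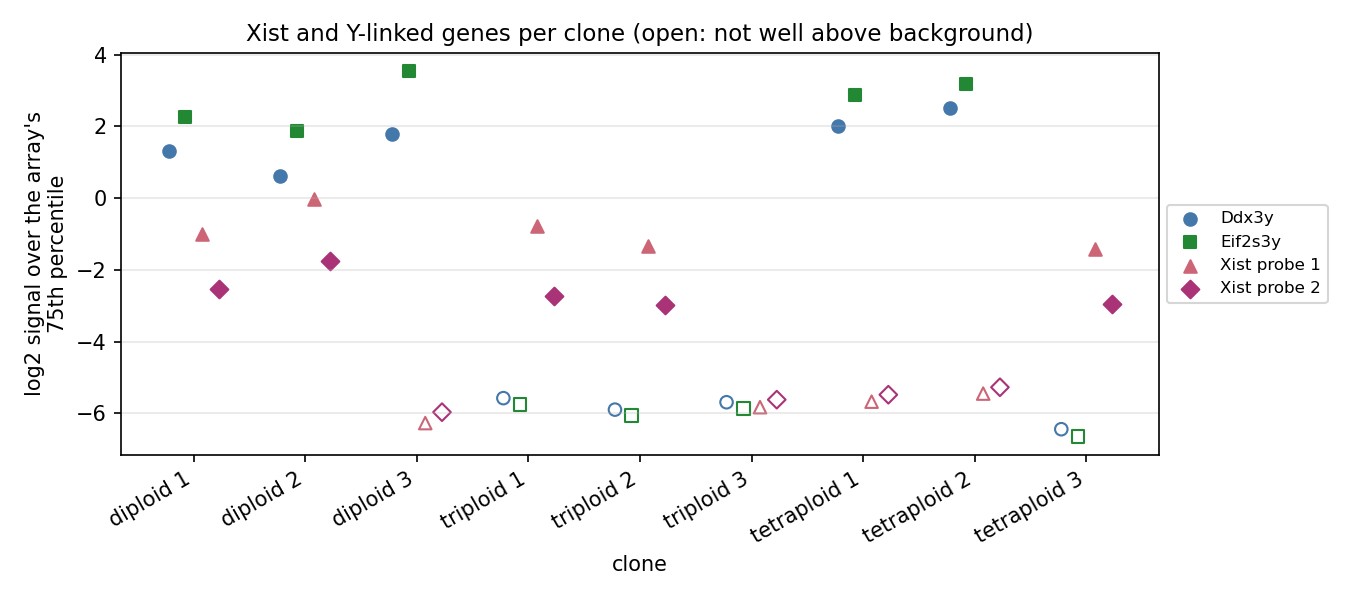
Log2 signal relative to the 75th percentile of each array for Xist, Ddx3y and Eif2s3y in the 9 clones; filled points were well above background and open points were not. All 3 triploid clones and tetraploid clone 3 lacked the Y-linked signal, and diploid clones 1 and 2 carried Xist and Y-linked signal together.

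The comparison of triploid with diploid clones asked what differs in cells with 1 extra chromosome set. Posterior HOX genes, fibroblast markers and TGF-beta targets were lower as lists in the triploid clones in camera at its preset correlation, and none of these lists passed with an estimated correlation. The triploid clones also lacked the Y-linked signal that all 3 diploid clones carried. Hoxa11, a transcription factor of limb and urogenital patterning, was at least 71.1-fold lower (log2 difference -8.15 ± 0.40, adjusted p = 4.03e-05, n = 3 clones per group). Hoxd13, which patterns digits and genital tract, was at least 126-fold lower (-9.20 ± 0.78, adjusted p = 0.00152). The microfibril protein gene Mfap5 was at least 337-fold lower. In the other direction, the alarmin Il33 was at least 22.2-fold higher (6.21 ± 0.66, adjusted p = 0.00448), and the protease inhibitor Slpi rose by a log2 difference of 6.63 ± 1.32 (adjusted p = 0.0465).

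In all, 400 features were called between triploid and diploid clones, 134 higher and 266 lower in triploid clones, with 87 and 174 of these being named genes. Of the 400, 395 had a fitted difference of more than 2-fold. They were counted without regard to bounds, and 110 of the 400 were dark on all arrays of the lower group. The genes with the largest fitted drops also included Hoxa11os, an antisense transcript of the Hoxa cluster (-8.02 ± 0.55), and Rspo2, a secreted enhancer of Wnt signalling (-7.51 ± 1.46). Smoc2, a matrix protein that binds calcium (-7.12 ± 0.73), and the water channel Aqp1 (-6.90 ± 1.37) followed. Coch, a secreted matrix protein, was at least 74.2-fold lower and Ccdc68 at least 70.2-fold lower. Among the largest rises were those of the copper carrier Cp (6.10 ± 1.20), and the haemoglobin scavenger Hp (5.51 ± 0.69). Saa3, a serum amyloid protein, was at least 5.66-fold higher. Other large rises were those of Plscr2 (4.14 ± 0.58), the inositol synthase gene Isyna1 (4.00 ± 0.81), Tent5c (3.67 ± 0.56), the cell adhesion receptor Cxadr (3.63 ± 0.73), and Mmp10, a matrix protease that was at least 7.30-fold higher. The adjusted p values of these genes lay between 0.000538 and 0.0487. With arrays on which a gene was dark set to the lowest signal called above background, the differences were -6.75 for Rspo2, -6.48 for Aqp1, 6.29 for Slpi and 5.44 for Cp.

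With slide as a block, which equals leaving out diploid clone 1, 81 features were called, 19 higher and 62 lower. Of the 81, 78 were among the 400. Of the 54 named genes called, which include the called members of lists named below, only 18 stayed past the threshold. Hoxa11, Hoxd13, Mfap5, Il33, Hp and Saa3 were among those that stayed. Coch, Rspo2, Aqp1, Slpi, Cp, Plscr2, Isyna1, Tent5c and Cxadr were among those that did not. In every fit with a clone left out, 15 of the 54 passed. The count of features called was 178 without diploid clone 2, 80 without diploid clone 3, 1434 without triploid clone 1, 61 without triploid clone 2, 75 without triploid clone 3 and 154 without tetraploid clone 1, and scaling to probes detected on all arrays gave 558, 119 higher and 439 lower, with a median over all genes of -0.05 against 0.10.

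**Figure D2:**
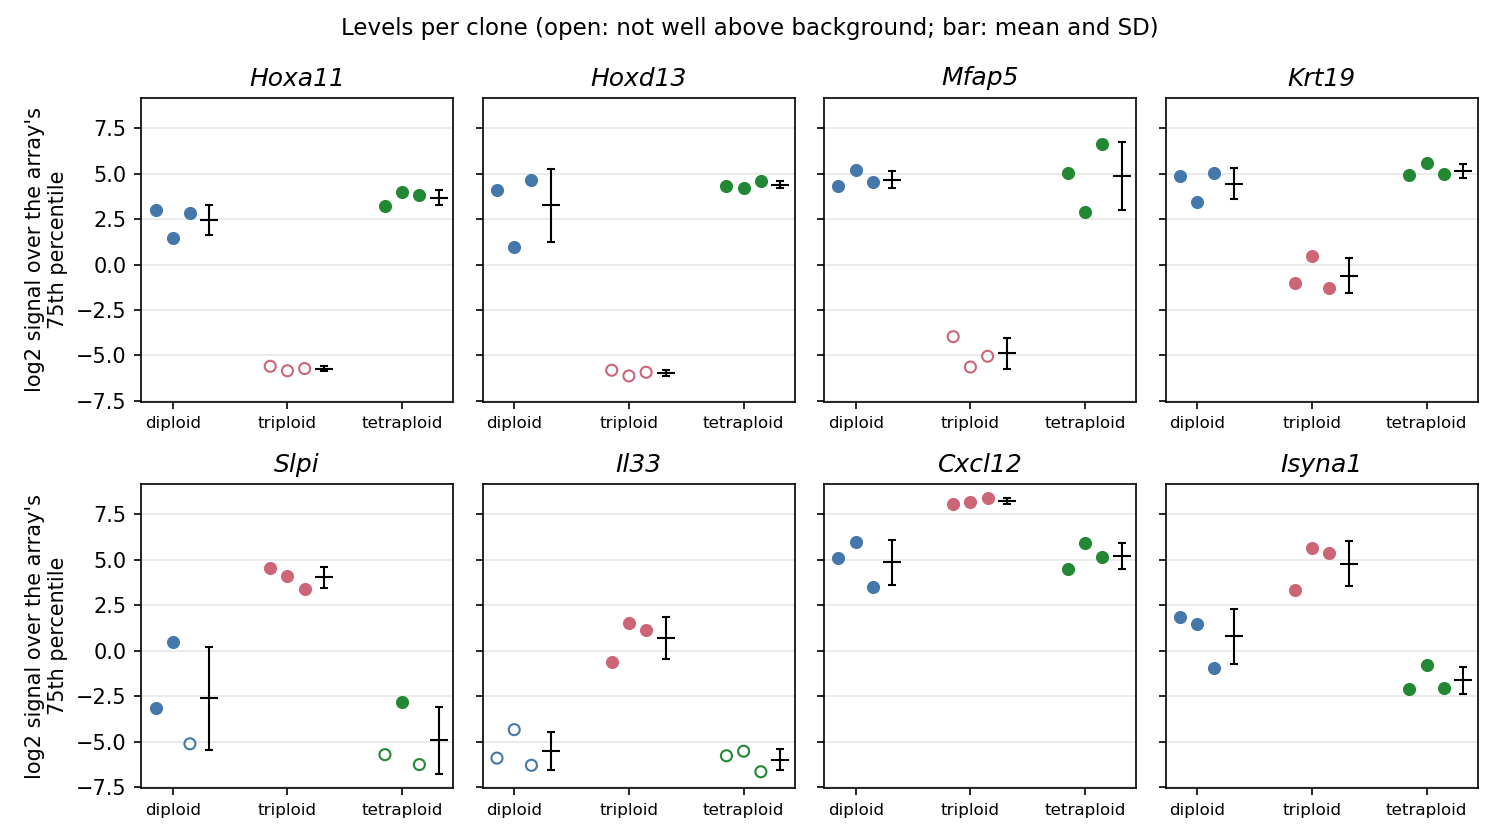
Log2 signal relative to the 75th percentile of each array for 8 genes named in the text, 1 point per clone, with the mean and SD of each group of 3; open points were not well above background. Hoxa11, Hoxd13, Mfap5 and Krt19 lay lower in all 3 triploid clones than in the other 6 clones, and Slpi, Il33, Cxcl12 and Isyna1 higher.

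Of the 44 gene lists tested, 20 passed camera between triploid and diploid clones, 12 higher and 8 lower. With an estimated correlation 0 passed, 6 passed fry, and 18 passed with slide as a block. Other splits of these arrays into groups of 3 passed up to 17 lists. List medians are given relative to the median of all features tested, called all genes here, which takes in the probes without a name. Lists were not tested against named genes alone. Posterior HOX genes, which specify distal and caudal positions, had 8 of 11 measured members lower, also when adjusted over the list alone, and a median of -4.32, or -3.98 with dark genes at their bound (adjusted p = 3.64e-11, and adjusted p = 0.0997 with an estimated correlation). With the slide block, and so without diploid clone 1, their median was -3.95 and 4 members were called lower. The number called lower was 7 without diploid clone 2, 6 without diploid clone 3, 5 without triploid clone 2 or 3 and 7 without tetraploid clone 1. Before the median of all genes was subtracted, the list's median was -4.23, and -2.43 with normexp background correction. Hoxd10 was at least 17.5-fold and Hoxd11 at least 15.3-fold lower.

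Targets of TGF-beta signalling and smooth muscle genes fell, with 4 of 22 members called and a median of -1.02 (adjusted p = 8.98e-06, and adjusted p = 0.0997 with an estimated correlation). Adjusted over the list alone, 10 were lower and 1 higher. They included the integrin gene Itga5 (-1.51 ± 0.22), the matrix protein Thbs1 (-1.88 ± 0.32) and the smooth muscle calponin Cnn1 (-2.77 ± 0.54). Fibroblast and mesenchyme markers had 2 of 27 members lower, Meox2 at least 11.7-fold and the transcription factor Snai2 by -1.65 ± 0.31, with a median of -0.93 (adjusted p = 1.44e-05, and adjusted p = 0.0997 with an estimated correlation). Adjusted over the list alone, 12 were lower and 2 higher. The Wnt pathway list fell, with a median of -0.75 (adjusted p = 0.00590, and adjusted p = 0.426 with an estimated correlation). Its called members, both lower, were the Wnt antagonist Dkk2 (-6.21 ± 0.72, or -5.33 with dark arrays at the lowest signal called above background) and Ccn5 (-4.12 ± 0.76); over the list alone 6 were lower and 2 higher. Epithelial markers fell through the keratins Krt19 (-5.08 ± 0.54) and Krt7 (-2.19 ± 0.43), with 2 of 11 members called and 3 over the list alone. Their median was -0.32 (adjusted p = 0.0170, and adjusted p = 0.544 with an estimated correlation). Collagens and matrix fell with 1 of 37 members called, Fbln5 of elastic fibres (-2.66 ± 0.28), 2 over the list alone and a median of -0.48 (adjusted p = 0.00842, and adjusted p = 0.667 with an estimated correlation). With the slide block, the call on collagens ended at an adjusted p of 0.0674.

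DNA replication genes rose, with a median of 0.56 over 49 members (adjusted p = 3.69e-09, and adjusted p = 0.614 with an estimated correlation). Pola2, a subunit of DNA polymerase alpha, was its only called member (1.25 ± 0.26), and 8 were higher adjusted over the list alone. Cohesin, condensin and chromosome separation genes rose with a median of 0.56 over 30 members (adjusted p = 1.01e-06, and adjusted p = 0.589 with an estimated correlation), with Cdca5, which protects cohesin, called (1.09 ± 0.21) and 9 higher over the list alone. Ribosome biogenesis (median 0.65, 30 members, 0 called in either count) rose with an adjusted p of 1.44e-05 and an adjusted p of 0.667 with an estimated correlation. The proteasome list (median 0.39, 33 members) rose with an adjusted p of 0.000816 and an adjusted p of 0.667 with an estimated correlation, although its only called member, Psmd8, was lower (-1.20 ± 0.22). Spindle checkpoint (median 0.26, 40 members, adjusted p = 0.00317) and G2/M regulators (0.37, 28 members, adjusted p = 0.00616) genes rose. Heat shock (0.31, 30 members, adjusted p = 0.00929), recombination and damage signalling (0.10, 39 members, adjusted p = 0.0128) and the unfolded protein response (0.17, 29 members, adjusted p = 0.0472) also rose. They had 0 called members, and adjusted over the list alone 3 G2/M regulators and 4 recombination genes were higher. Of these 5 lists, the unfolded protein response had an adjusted p of 0.698 with an estimated correlation and the other 4 had 0.667. The unfolded protein response passed in 11 of 21 other settings of camera at the preset correlation, with a highest adjusted p of 0.276, and each of the other 4 in at least 20. The 21 settings count the slide block and the fit without diploid clone 1 apart, although they are the same fit.

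NF-kB targets and cytokines rose, with 4 of 28 members higher, 7 higher and 2 lower over the list alone and a median of 0.62 (adjusted p = 0.0127, and adjusted p = 0.544 with an estimated correlation). Besides Il33 and Saa3 these were the chemokines Cxcl12 (3.37 ± 0.57) and Cxcl1 (2.49 ± 0.48). Antigen presentation had 2 of 17 higher, 6 over the list alone, and a median of 0.64 (adjusted p = 0.00317, and adjusted p = 0.551 with an estimated correlation): Tapbp, which loads peptides onto class I molecules (1.56 ± 0.28), and the class I gene H2-M3 (3.17 ± 0.61). In mismatch and excision repair, the called members among 35 included Ddb2, which rose (1.32 ± 0.26), and Ercc1, which fell (-1.87 ± 0.25), with 6 higher and 1 lower over the list alone and a median of 0.46 (adjusted p = 0.0128, and adjusted p = 0.604 with an estimated correlation). Growth factor and MAPK response genes (median -0.35, adjusted p = 0.0387) and autophagy genes (-0.24, adjusted p = 0.0453) fell with 0 members called (adjusted p = 0.604 and 0.698 with an estimated correlation), and the former ended at an adjusted p of 0.0976 with the slide block and passed in 15 of the 21 other settings.

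Among the 24 other lists, which did not pass, the p53 target list had 1 of 31 members higher, Ddb2, and a median of -0.17 (adjusted p = 0.495). In the apoptosis list (median 0.16, adjusted p = 0.121), the genes of the cell death inducers Bmf (2.26 ± 0.27) and Bcl2l11 (1.89 ± 0.33) rose. The bone, cartilage and fat markers Fabp4 (-5.35 ± 0.83) and Col10a1 (-4.45 ± 0.85, or -3.40 with dark arrays at the lowest signal called above background) fell, while Cebpb rose (1.38 ± 0.24), in a list with a median of -0.91 (adjusted p = 0.0544). The interferon regulator Irf1 (1.35 ± 0.22), the metallothionein Mt2 (2.23 ± 0.44) and the cell cycle factor Tfdp2 (1.34 ± 0.24) rose, and the transcription factor Klf2 fell (-2.86 ± 0.49).

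**Figure D3:**
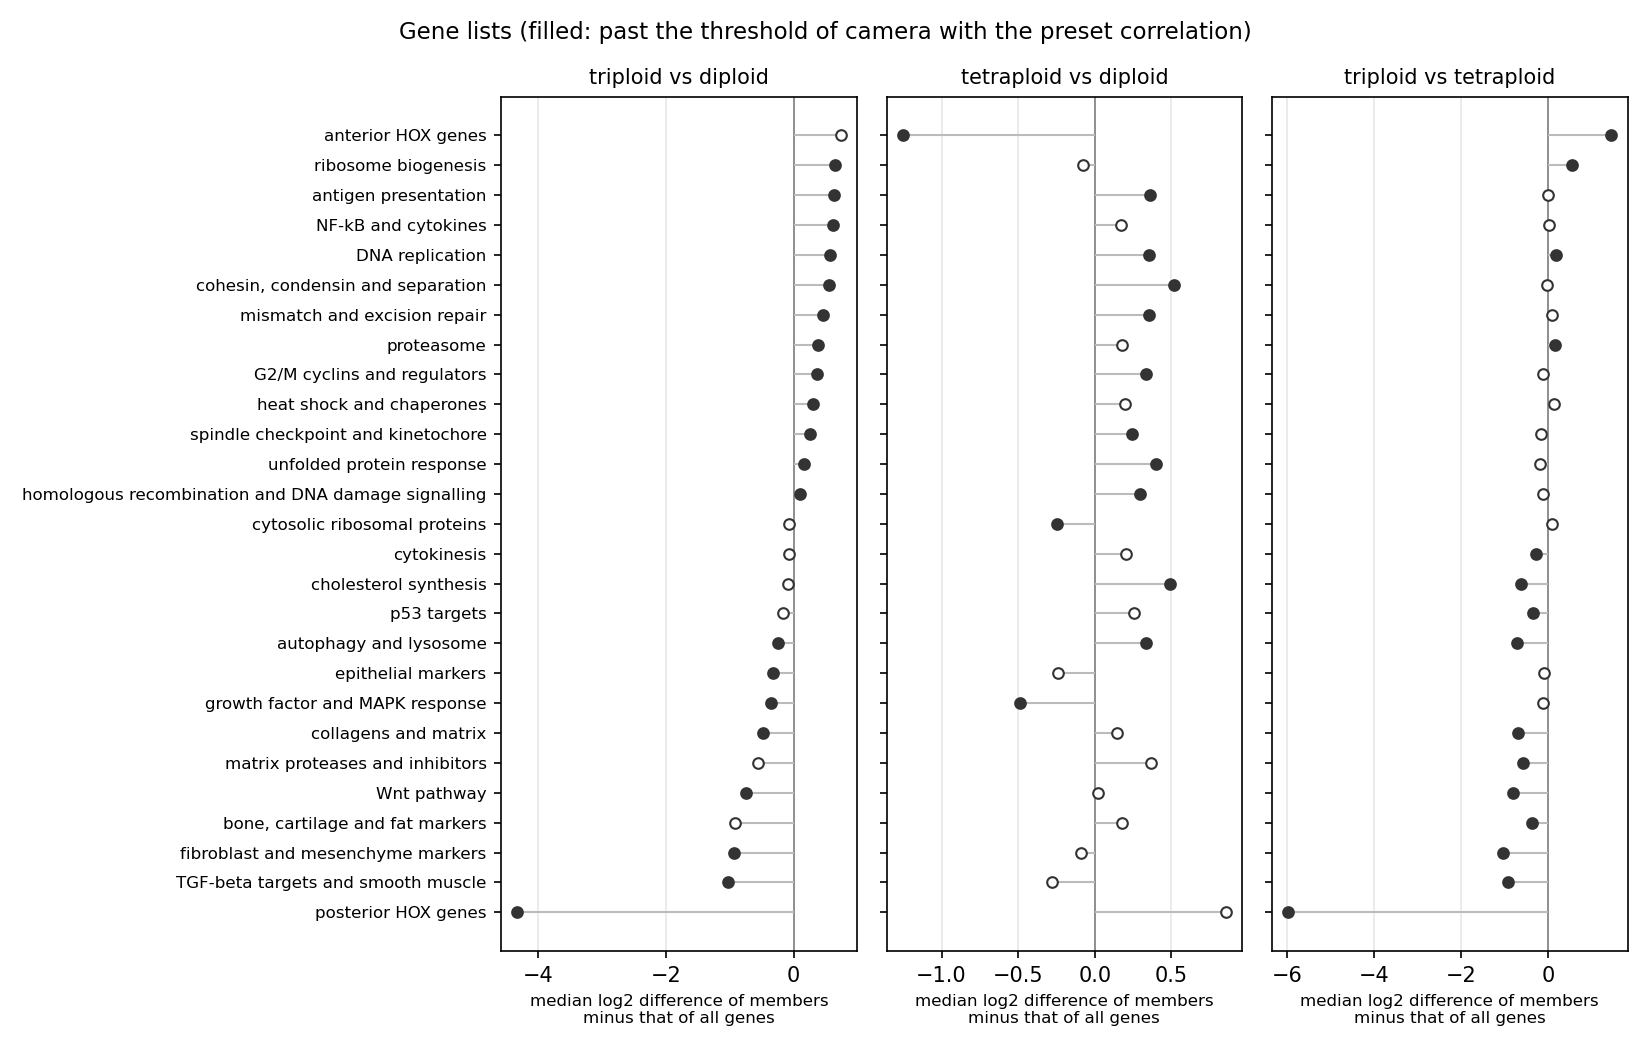
Median log2 difference relative to all genes for the tested gene lists that passed in any pair of ploidies, with a separate x scale in each panel; filled points passed camera at the preset correlation. Of the lists shown, posterior HOX genes lay lowest in both comparisons that involve triploid clones, at -4.32 against diploid and -5.97 against tetraploid clones (-3.98 and -3.87 with dark genes at their bound).

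The comparison of tetraploid with diploid clones asked what differs in cells with doubled chromosome sets. Few genes passed: 16 features were called, all lower in tetraploid clones, of which 6 were named genes. The nucleoporin-like gene Nup62cl was at least 4.80-fold lower (-4.35 ± 0.57, adjusted p = 0.0458), the protocadherin gene Pcdh20 at least 4.76-fold (-4.16 ± 0.51, adjusted p = 0.0383), and the amino acid transporter gene Slc43a1 at least 4.95-fold (n = 3 clones per group in this limma fit). Mycl, of the Myc family of transcription factors, was at least 1.68-fold lower, the placental lactogen Prl3d1 fell by a log2 difference of -2.53 ± 0.33, and Cracd, a regulator of actin capping, by -2.10 ± 0.21 (adjusted p = 0.0317). Of genes higher in tetraploid clones, 0 passed in limma, and 3226 features in either direction had an unadjusted p below 0.05. The 5 named genes of smallest p in that direction were Cldn19 (3.25 ± 0.50, adjusted p = 0.0648), Tapbp (1.74), Vegfd (1.72), Foxf2 (1.44) and Ddx50 (1.29).

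With slide as a block 0 features were called, and none of the 6 genes passed. Without diploid clone 2 the count was 1, without diploid clone 3 it was 40, without tetraploid clones 1, 2 and 3 it was 3, 0 and 1, without triploid clones 1 and 2 it was 28 and 0, and scaling to probes detected on all arrays gave 97, 3 higher and 94 lower.

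Of the 44 lists, 13 passed camera between tetraploid and diploid clones, 10 higher and 3 lower, 16 did so with slide as a block, and 0 did so with an estimated correlation or in fry. At least 13 passed in 7 of 10 splits of these arrays into groups of 3, the real one included. The count of lists thus does not set the real groups apart. Members called over all genes numbered 0 in each; adjusted over the list alone, 1 G2/M regulator and 1 antigen presentation gene were higher and 1 mismatch repair gene was lower. The adjusted p with an estimated correlation was 0.738 for ribosomal proteins and 0.628 for the other 12. Cohesin, condensin and chromosome separation genes rose with a median of 0.52 (adjusted p = 1.22e-05), cholesterol synthesis genes with 0.49 and 7 of 25 members higher adjusted over the list alone (adjusted p = 2.58e-05), and DNA replication genes with 0.36 (adjusted p = 9.17e-05). Spindle checkpoint genes (0.24), the unfolded protein response (0.40), G2/M regulators (0.34), autophagy (0.33), mismatch repair (0.35), recombination (0.30) and antigen presentation (0.36) rose too, at adjusted p values of 0.000257 to 0.00589. Anterior HOX genes fell, with a median of -1.25 over 10 members (adjusted p = 0.00695), as did MAPK response genes (-0.49, adjusted p = 0.0108) and cytosolic ribosomal proteins (-0.25 over 59 members, adjusted p = 0.0108). The MAPK call ended at an adjusted p of 0.0503 with slide as a block, and the MAPK and ribosomal protein lists each passed in 17 of the 21 other settings. Probes without a name that the array design places lay lower than named genes in the tetraploid clones, which tilts these medians upward. Chromosome 7, for instance, was at -0.14 relative to all features and at -0.25 relative to named genes placed on chromosomes. Small rises of lists, and their excess over falls, may thus reflect the reference.

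The comparison of triploid with tetraploid clones asked whether the triploid state differs from another polyploid state. Posterior HOX genes were again lower in triploid clones: Hoxd13 at least 277-fold (-10.34 ± 0.78, adjusted p = 0.000855, n = 3 clones per group in limma), Hoxa11 at least 169-fold (-9.40 ± 0.40, adjusted p = 3.32e-05). Mfap5 was at least 383-fold lower. The opioid precursor Penk fell by a log2 difference of -11.11 ± 2.14 (adjusted p = 0.0334, and 0.0608 with slide as a block), and Ahrr, the repressor of the aryl hydrocarbon receptor, was at least 55.9-fold lower. Slpi (8.96 ± 1.32, adjusted p = 0.0139) and Isyna1 (6.42 ± 0.81) rose, and Il33 was at least 22.9-fold higher.

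In this comparison 589 features were called, 237 higher and 352 lower in triploid clones, with 116 and 296 named genes, and 139 were dark in the lower group. Other large drops were those of Hoxa11os (-9.23 ± 0.55), Rspo2 (-8.53 ± 1.46), the hypertrophic cartilage collagen Col10a1 (-8.40 ± 0.85), Aqp1 (-8.23 ± 1.37) and Smoc2 (-7.88 ± 0.73). Of the genes that rose, Lsr, a protein of tricellular junctions, was at least 25.2-fold higher and Inava, which acts at epithelial junctions, at least 29.7-fold. Rab38, which sorts pigment enzymes, was at least 21.9-fold and Ctla2b at least 29.1-fold higher, and Cp (5.96 ± 1.20), Tmem37 (5.83 ± 1.26) and Prss12 (5.47 ± 0.88) rose. With dark arrays at the lowest signal called above background, the differences were -10.14 for Penk, -7.80 for Aqp1, -7.76 for Rspo2, -7.35 for Col10a1, 7.66 for Slpi and 4.17 for Prss12. Without diploid clone 1 and so with slide as a block, 284 were called, 112 higher and 172 lower, 275 of them among the 589. Of the 66 named genes called, 47 stayed past the threshold. Those that did not included Penk, Lsr, Ctla2b, Tmem37, Cp, Hoxd4, Sfrp2, Psap, Nsdhl and Plk3. The count was 147 without tetraploid clone 1, 918 without tetraploid clone 2, 140 without tetraploid clone 3, 1312 without triploid clone 1, 136 without triploid clone 2 and 117 without triploid clone 3. Of the 66 named genes called, 21 passed in every fit with a clone left out.

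Of the 44 lists, 15 passed between triploid and tetraploid clones, 4 higher and 11 lower. With slide as a block 15 passed, 0 with an estimated correlation and 5 in fry. At least 15 passed in 6 of 10 splits of these arrays into groups of 3, the real one included, so the count does not set the real groups apart. Posterior HOX genes had 7 of 11 members lower, 8 over the list alone, and a median of -5.97, or -3.87 with dark genes at their bound (adjusted p = 4.87e-12, and adjusted p = 0.164 with an estimated correlation). Before the median of all genes was subtracted it was -5.81, and -2.48 with normexp background correction. Anterior HOX genes rose, with a median of 1.45 (adjusted p = 0.0104, and adjusted p = 0.736 with an estimated correlation); Hoxd4 was called (3.65 ± 0.75), and over the list alone 6 were higher and 1 lower. Fibroblast markers fell, with 4 of 27 called, 12 lower and 3 higher over the list alone and a median of -1.04 (adjusted p = 0.000308, and adjusted p = 0.192 with an estimated correlation); Ly6a (-6.20 ± 0.99) and Snai2 (-2.24 ± 0.31) were among them. TGF-beta targets fell with 2 of 22 called, 5 over the list alone and a median of -0.92 (adjusted p = 5.15e-05, and adjusted p = 0.192 with an estimated correlation). Bone, cartilage and fat markers fell with 4 of 13 called, 5 lower and 1 higher over the list alone and a median of -0.37 (adjusted p = 0.00944, and adjusted p = 0.192 with an estimated correlation). They were Col10a1, the fat cell genes Fabp4 (-6.49 ± 0.83) and Pparg (-3.29 ± 0.56), and the cartilage protein Comp, at least 22.6-fold lower.

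Wnt pathway genes fell in the same comparison, with 4 lower and 1 higher of 27, 8 and 2 over the list alone, and a median of -0.80 (adjusted p = 0.00276, and adjusted p = 0.253 with an estimated correlation); Sfrp2 fell (-3.92 ± 0.73) and the ligand Wnt5b rose (2.75 ± 0.49). Collagens fell with 4 of 37 called, 10 lower and 3 higher over the list alone and a median of -0.69 (adjusted p = 0.00390, and adjusted p = 0.736 with an estimated correlation), among them Lum, at least 7.98-fold. Autophagy and lysosome genes fell with 1 of 38 called, the saposin precursor Psap (-1.23 ± 0.25), 2 over the list alone and a median of -0.72 (adjusted p = 2.59e-06, and adjusted p = 0.677 with an estimated correlation). Cholesterol synthesis fell with 1 of 25 called in both counts, Nsdhl (-1.65 ± 0.32), and a median of -0.61 (adjusted p = 0.000213, and adjusted p = 0.736 with an estimated correlation). Matrix proteases fell with 2 lower and 1 higher of 27, 5 and 2 over the list alone, and a median of -0.59 (adjusted p = 0.00390, and adjusted p = 0.677 with an estimated correlation). The p53 target list fell with a median of -0.35 (adjusted p = 0.0327, and adjusted p = 0.677 with an estimated correlation), although its only called member, the kinase Plk3, was higher (1.11 ± 0.22); over the list alone 1 was higher and 2 lower, and the list passed in 16 of the 21 other settings. Cytokinesis genes fell with a median of -0.27 and 0 called (adjusted p = 0.0223, and adjusted p = 0.736 with an estimated correlation). Ribosome biogenesis rose with a median of 0.56, 0 called and 7 over the list alone (adjusted p = 2.27e-05, and adjusted p = 0.736 with an estimated correlation). DNA replication (0.19, adjusted p = 0.0216) and the proteasome (0.16, adjusted p = 0.0301) rose with 0 called, both with an adjusted p of 0.945 with an estimated correlation. In this comparison the probes without a name tilt list medians downward. Chromosome 7 was at -0.30 relative to all features and at -0.16 relative to named genes placed on chromosomes. Small falls of lists, and their excess over rises, may thus reflect the reference.

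Set against the mean of the diploid and tetraploid groups, triploid clones had 691 features called, 261 higher and 430 lower, with 153 and 342 named genes. Among the drops, Hoxd13 was at least 186-fold lower, Mfap5 at least 359-fold and Hoxa11 at least 110-fold (adjusted p = 7.31e-06, limma over 9 clones), and Hoxa11os (-8.63 ± 0.48) and Rspo2 (-8.02 ± 1.26) fell. Among the rises, Il33 was at least 22.5-fold higher, and Slpi (7.79 ± 1.14), Cp (6.03 ± 1.04), Isyna1 (5.21 ± 0.70) and Hp (5.00 ± 0.60) rose. The G1 cyclin Ccnd1 (-1.74 ± 0.38), the hypoxia-induced hormone Adm (-5.90 ± 1.32) and the neuronal protein Stmn2 (-5.99 ± 1.35) fell. The receptor kinase Met (1.87 ± 0.40) and the cohesin subunit Smc3 (0.90 ± 0.19) rose. With slide as a block, the calls on Ccnd1, Adm, Stmn2 and Smc3 ended, at adjusted p values of 0.0907, 0.0924, 0.0975 and 0.0507, and each of these 5 genes passed in 2 or 3 of the 9 fits with a clone left out. With dark arrays at the lowest signal called above background, the differences were -7.26 for Rspo2, 6.98 for Slpi, 5.70 for Cp, -5.81 for Adm and -4.60 for Stmn2. Lists passing camera numbered 13, 5 higher and 8 lower, 12 with slide as a block, 0 with an estimated correlation and 6 in fry. Of 100 splits of all 9 arrays, the real one included, 60 passed at least 13. Posterior HOX genes had 8 of 11 lower and a median of -5.15, or -3.93 with dark genes at their bound (adjusted p = 1.84e-12, and adjusted p = 0.0976 with an estimated correlation). With slide as a block, which leaves out diploid clone 1, 322 features were called, 115 higher and 207 lower, 305 of them among the 691. The count was 417 without diploid clone 3, 312 without tetraploid clone 1, 1208 without tetraploid clone 2, 1627 without triploid clone 1, 164 without triploid clone 2 and 127 without triploid clone 3. Named genes called in this comparison numbered 66, and 22 of them passed in every fit with a clone left out.

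A test for any difference among the 3 ploidies called 518 features, 327 of them named genes. It called 173 without diploid clone 1, and so with slide as a block, 308 without diploid clone 2 and 341 without diploid clone 3. It called 176 without tetraploid clone 1, 208 without tetraploid clone 3, 1461 without triploid clone 1, 75 without triploid clone 2 and 89 without triploid clone 3.

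To ask whether both polyploid states shared changes from diploid clones, the calls of both comparisons were overlapped. They shared 9 features, all lower in both: Cracd, Nup62cl, Pcdh20 and 6 probes without a name. In 100 simulations of no change with the same shared diploid controls, the number of shared calls averaged 0 and reached at most 0. With no change simulated, hardly any gene can be called, so this count was all but fixed beforehand. Independent lists of these sizes would share 0.195 lower calls, a figure that leaves out the shared controls. Neither number tells how many shared calls the diploid arrays in common would give by themselves. Over all genes, which are not independent, the 2 sets of log2 differences correlated at 0.27, against 0.50 in simulations where the shared controls alone tie them, while their covariance was 0.167, against 0.0953. Without diploid clone 1, and so with slide as a block, 0 were shared. The number was 1 without diploid clone 2, 17 without triploid clone 1, 0 without triploid clone 2, 3 without tetraploid clone 1, 0 without tetraploid clone 2 and 1 without tetraploid clone 3, and scaling to probes detected on all arrays gave 39.

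Because ploidy concerns whole chromosomes, expression was summarised per chromosome. Between triploid and diploid clones, 8 of 20 chromosomes passed. Chromosome 7 was lower (-0.29 ± 0.08, adjusted p = 0.0152, limma), and chromosomes 19 (0.35 ± 0.08, adjusted p = 0.00958), 17 (0.32), 15 (0.32), 8 (0.31), 6 (0.28), 5 (0.28) and 2 (0.27) were higher, where the median over all genes was 0.10. Taken per array relative to the median of all genes placed on chromosomes, 9 passed: chromosomes 7 (-0.41), 12 (-0.37) and 10 (-0.21) lower and chromosomes 19 (0.24), 17 (0.21), 8 (0.19), 6 (0.17), 5 (0.17) and 2 (0.15) higher, with chromosome 15 at an adjusted p of 0.0542. Without this centring and with slide as a block, which leaves out diploid clone 1, 0 passed, at adjusted p values of 0.0657 to 0.0718 for these 8; 0 passed without diploid clone 2 or triploid clone 3 and 1 without triploid clone 2. Scaling to probes detected on all arrays called 5: chromosomes 17 and 19 higher and chromosomes 7, 10 and 12 lower. Between tetraploid and diploid clones 0 chromosomes passed in limma, with 3 at an unadjusted p below 0.05; without tetraploid clone 3, chromosomes 8, 10 and 15 passed, all higher. Between triploid and tetraploid clones 0 passed, with 4 at an unadjusted p below 0.05; 5 passed without triploid clone 1 and 1 without tetraploid clone 3, and relative to the median of all genes 3 passed, chromosomes 2 and 19 higher and chromosome 10 lower.

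Single clones were set against random gene sets. Against the diploid mean, the median of a chromosome lay beyond all 10000 random gene sets of its size for 11, 15 and 13 chromosomes in triploid clones 1 to 3 and for 5, 9 and 7 in tetraploid clones 1 to 3. For diploid clones, each against the other 2, the number was 0, though chromosome 7 in diploid clone 1 lay at percentile 0.12 of its random sets. These counts are not like for like, since diploid clones were set against their own group and polyploid clones against another. No polyploid clone was set against its own group. Chromosome 7 was lower in 6 of 6 polyploid clones, at -0.21, -0.52 and -0.44 in the triploid and -0.22, -0.33 and -0.18 in the tetraploid clones, which share the diploid reference. Chromosome 8 lay above all random sets in 5 of the 6 clones and chromosomes 3 and 15 in 4, with 0.44 for chromosome 15 in tetraploid clone 2, and chromosome 4 lay below them in 4. The medians of chromosomes 3, 5, 8, 15 and 17 were above 0 in all 6 clones and those of chromosomes 1, 7 and 12 below. Chromosome 12 was at -0.70 in triploid clone 1, -0.29 in triploid clone 2 and -0.23 in tetraploid clone 3. The X chromosome was at -0.56 and -0.41 in triploid clones 2 and 3 and at 0.12 in triploid clone 1.

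**Figure D4:**
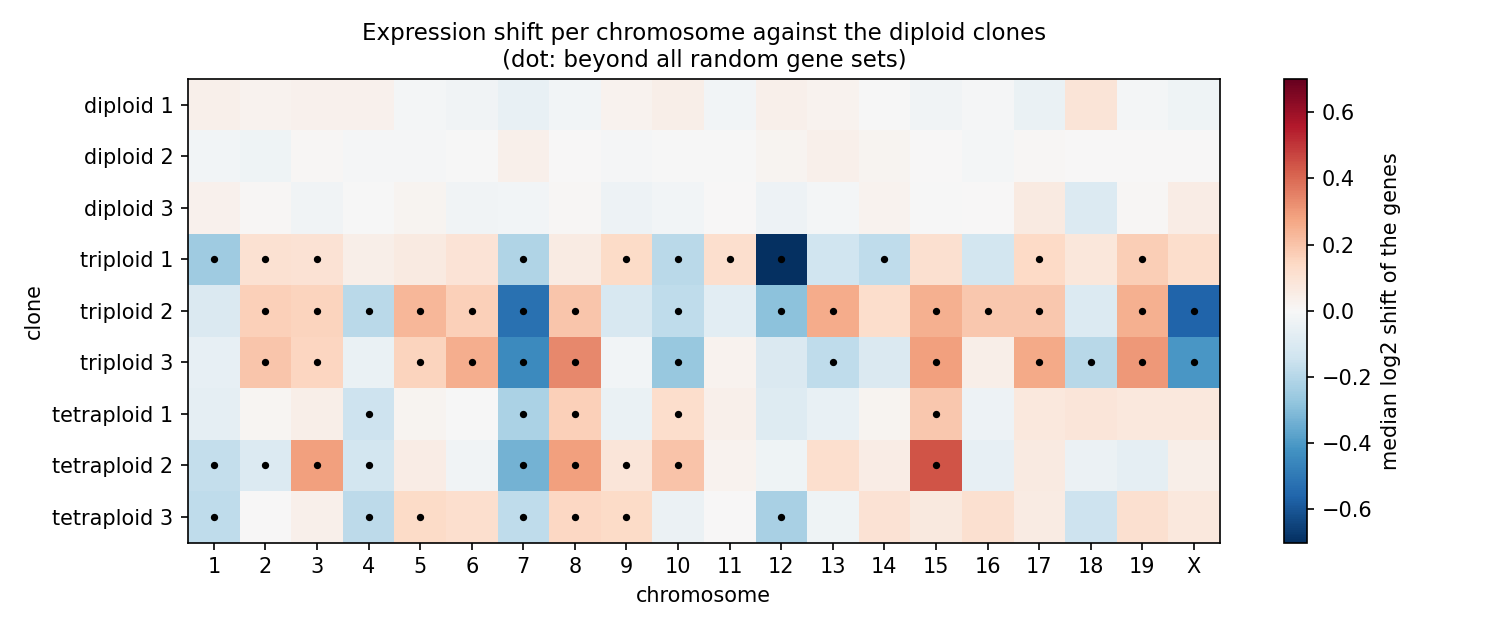
Median log2 difference of the genes of each chromosome from the diploid mean, per clone (for a diploid clone, from the other diploid clones), after centring each clone on its median over all genes; marked cells lay beyond all 10000 random gene sets. The 3 diploid clones had 0 such chromosomes and the 6 polyploid clones 5 to 15. Diploid clones were set against their own group and polyploid clones against another, so these counts are not like for like.

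Whether polyploid clones varied more among themselves than diploid clones was tested on the distance of each clone from its group mean, as a root mean square over all features. It was 0.432 ± 0.0544 (SD, n = 3) in diploid, 0.530 ± 0.137 in triploid and 0.489 ± 0.119 in tetraploid clones. In two-sided exact permutation tests, p was 0.5 for triploid against diploid, 0.5 for tetraploid against diploid and 0.8 for triploid against tetraploid, where 3 clones against 3 cannot go below 0.1.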

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

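Both the search below and the genes named from it were chosen after the values were seen.

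Bright signal appeared in polyploid clones at probes outside every comparison, since no group had them above background on all 3 arrays. Among 30129 such probes, those counted were above background in the clone, dark in all 3 diploid clones, and at least 4-fold above the highest diploid value or the lowest level called above background. There were 37 in triploid clone 1, 106 in triploid clone 2 and 223 in triploid clone 3, and 138, 181 and 74 in tetraploid clones 1, 2 and 3. By the same rule against the other 2 diploid clones, diploid clones 1 to 3 had 68, 213 and 19.

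Triploid clones 2 and 3 had several of these genes in common. The iron carrier Trf was at least 209-fold and 70.1-fold above the diploid clones, Tcf21, a transcription factor of mesothelial and mesenchymal lineages, at least 118-fold and 122-fold, and Scel, a protein of the cornified envelope, at least 95.3-fold and 64.8-fold. Triploid clone 2 also held Sfrp4, a secreted Wnt modulator (at least 131-fold), and the receptor kinase Mst1r (at least 105-fold). Triploid clone 3 held the aldehyde dehydrogenase Aldh3a1 (at least 138-fold) and Gata4, a transcription factor of heart and endoderm (at least 57.7-fold). These genes were not particular to the clone named. Aldh3a1 was above background on 4 arrays, Mst1r on 3, and Sfrp4 and Gata4 on 2, none of them diploid. In triploid clone 1 the highest bound was at least 10.9-fold, at Gprasp2. Among tetraploid clones, clone 1 held Krtap6-1 (at least 19.1-fold), clone 2 the homeobox genes Vax1 and Cdx1 (at least 23.7-fold and 20.2-fold) and the endothelial receptor Tie1 (at least 21.4-fold), and clone 3 the ferritin receptor Scara5 (at least 53.5-fold) and the claudin Cldn10 (at least 24.4-fold). Gprasp2, Vax1, Cdx1 and Scara5 were above background on 2 arrays, and Krtap6-1, Tie1 and Cldn10 on 1.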

How the results depend on the processing

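Scaling to probes detected on all arrays, centring on the median of tested genes, chromosome medians relative to all genes placed on chromosomes and tests of named genes alone were chosen after the results were seen; the other alternatives were not. Of 4717 checks on 203 results for named genes, 3707 kept direction and side of the threshold, 988 kept the direction and lost the call, 18 gained a call and 4 reversed. These checks count the fixed slide block and the fit without diploid clone 1 apart, although they are the same fit. The deposited table and the random slide block, with a correlation of 0.0128, could hardly differ from the main fit. The reversals concerned Ddx3y and Eif2s3y between tetraploid and diploid clones, neither of them called: with each clone left out in turn, Ddx3y ranged from -3.46 to 1.01 and Eif2s3y from -4.45 to 0.47, the highest without tetraploid clone 3, and array weights gave 0.98 and 0.56.

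With each clone left out in turn, genes called ranged from 61 to 1434 for triploid against diploid, 0 to 40 for tetraploid against diploid, 117 to 1312 for triploid against tetraploid, 127 to 1627 for triploid against the mean of the others and 75 to 1461 for any difference. Lists ranged from 15 to 24, 13 to 16, 10 to 16 and 12 to 16 in the first 4 of these, chromosomes from 0 to 11, 0 to 3 and 0 to 5 in the first 3, and shared calls from 0 to 17. A fixed slide block equals the fit without diploid clone 1: it called 81, 0, 284, 322 and 173 genes in the same order, 0 chromosomes for triploid against diploid, and 0 shared. A random slide block gave within 1.5 times each gene count; for lists it was not run, since camera takes no random block. Clone number as a block called 219 genes for triploid against diploid and 0 for tetraploid against diploid, with 0 shared, and leaves fewer degrees of freedom. Fits on 2 groups alone, with fewer arrays for the spread, called 206 for triploid against diploid and 369 for triploid against tetraploid.

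Without a filter on dim probes, which adds many features to the adjustment, 103, 0, 198, 260 and 153 genes were called, 21 lists for tetraploid against diploid and 0 shared. Of probes above background on all 9 arrays, 4 were shared. Tests of named genes alone, on fewer features, called 261 for triploid against diploid, 1 for tetraploid against diploid and 303 for any difference, with 1 shared. For the settings that follow the cause was not tested. Scaling to probes detected on all arrays called 97 genes for tetraploid against diploid and 795 for any difference, 5 chromosomes for triploid against diploid and 1 for triploid against tetraploid, with 39 shared. Quantile normalization called 5 genes for tetraploid against diploid and 1 chromosome for triploid against tetraploid, with 3 shared. Normexp called 9 genes and 21 lists for tetraploid against diploid. Means over chromosomes called 2 for triploid against tetraploid, and chromosome medians relative to all genes called 3.

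Array weights called 4178, 5358, 8728, 6296 and 10830 genes, 8 lists for tetraploid against diploid and 1350 shared; the fit of the weights did not converge and gave tetraploid clone 1 a weight of 72.7, so these counts rest on that clone. Camera with an estimated correlation passed 0 lists in each of the 4 comparisons, and fry, which does not compare a list with other genes, passed 6, 0, 5 and 6. Signal over background limits the folds: 110 of 400 and 139 of 589 calls were dark in the lower group, and for those only bounds hold.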

Other observations

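Chosen after the result was seen were the tests on Xist and Y-linked signal and the tests of dim arrays, of ploidy as such and of mixed cultures for the HOX genes, and the test of scaling for the chromosomes; the tests of scaling for the HOX genes, of regions, probe sets and splits were not.

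Between triploid and tetraploid clones, called genes also stood in lists that did not pass camera. Dusp6, a phosphatase that acts on ERK, and Spred2, an inhibitor of Ras signalling, rose in triploid clones, by log2 differences of 2.41 ± 0.48 and 1.17 ± 0.24, in a MAPK list with a median of -0.12 relative to all genes (adjusted p = 0.861, limma's camera). In the glycolysis list, the regulator Pfkfb3 rose (2.76 ± 0.42) and the hexokinase Hk1 fell (-1.54 ± 0.24), with a median of -0.17 (adjusted p = 0.296). The interferon-induced Ifit3 fell (-3.58 ± 0.55), in a list with a median of -0.15 (adjusted p = 0.671). Of neural and glial markers, the myelin gene Mbp rose (4.99 ± 0.93) and S100b was at least 18.2-fold lower, with a list median of -0.05 (adjusted p = 0.471). The endothelial von Willebrand factor gene Vwf was at least 3.83-fold lower in triploid clones. The cell death inducers Bcl2l11 (2.20 ± 0.33) and Bmf (1.81 ± 0.27) rose here as they did against diploid clones. With slide as a block, Dusp6, Spred2, Mbp and Vwf did not stay past the threshold.

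Diploid clones 1 and 2 carried Xist together with Y-linked transcripts. Both Xist probes were above background, or both were not, on 9 of 9 arrays, which argues against cross-hybridisation of one Xist probe. A culture that mixes cells with Y and cells with Xist is a candidate explanation: the 4 values of Ddx3y and Eif2s3y on these 2 arrays lay below those of every array with Y-linked signal and no Xist. Only 3 arrays formed that comparison, diploid clone 3 and tetraploid clones 1 and 2, and both genes come from the same arrays, so it is weak. Mixing of RNA after harvest and cells that carry a Y and more than 1 X chromosome stay open, as neither was tested.

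Posterior HOX genes were low in all 3 triploid clones, with 4, 4 and 5 of 11 above background, against 11 in each diploid clone and 9, 11 and 11 in the tetraploid clones. Failed or dim triploid arrays are argued against, since all 3 had a larger share of bright spots (47.5% to 50.8%) than tetraploid clone 2 (44.8%), which had all 11 HOX genes above background, and so is scaling, since the median difference was -2.43 or lower under every scaling and background correction tried. A rise in ploidy as the whole cause is argued against by the 8 HOX genes called lower than in diploid clones, all 8 of which were above background in all 3 tetraploid clones. Triploid clones grown from a part of the mixed diploid cultures stay open: 2 of 2 diploid clones with Xist lay nearer to them than diploid clone 3 did, by medians of -0.60 and -1.48 at 213 genes low and 0.72 and 1.29 at 156 genes high in triploid against tetraploid clones, where all genes gave -0.08 and -0.06. Triploid clone 3, however, was dark at both Xist probes (-5.83 and -5.62) while sharing the low HOX genes, and tetraploid clone 3, with Xist and no Y-linked signal, had all 11 HOX genes above background. An effect of the triploid state itself stays open too, since ploidy and clone history cannot be separated here.

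Medians over the named genes of many chromosomes shifted in single polyploid clones. Between groups, limma called 8 chromosomes for triploid and 0 for tetraploid against diploid clones. A constant scaling of the arrays is argued against by the gap between the highest and lowest chromosome median of a clone, which no constant added to an array alters. With the main scaling it was 0.37 to 0.87 in the polyploid clones and 0.07 to 0.16 in the diploid clones. It exceeded all 1000 shuffles of genes over chromosomes in 6 of 6 polyploid and 0 of 3 diploid clones, with the main scaling and with quantile normalization. Shuffles were narrow for diploid clones too. With the main scaling, 16, 549 and 7 of 1000 were as large in diploid clones 1 to 3. With quantile normalization, 12, 838 and 120 were. A few regions as the source are argued against by the medians of the proximal and distal parts of the 20 chromosomes, split at the middle gene. They correlated at Spearman's rho of 0.608 to 0.923 in the polyploid clones, against -0.239 to 0.281 in diploid clones. For gaps and correlations alike, diploid clones were set against their own group and polyploid clones against the diploid clones. The contrast of diploid with polyploid clones thus cannot tell shifts of single clones from a difference between groups. Whether the named genes' probes bear on the pattern cannot be told apart from a real shift: at 4410 unnamed probes placed by the array design, rho with the named genes was 0.186 to 0.516 in the polyploid clones, and 0.170 to 0.531 in the diploid clones, which had no chromosome beyond all random sets, so the test does not separate them. Gains and losses of single chromosomes in clones are a candidate explanation in line with the likeness of both parts, yet no DNA content or karyotype was analysed here.

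The comparisons were repeated on other splits of the arrays into groups of the same sizes. With 3 clones against 3 there are 10 splits, the real one included, too few for a share under 0.05. For triploid against diploid clones the real split called 400 genes, 20 lists and 8 chromosomes, and the highest of the others 2, 17 and 0. For tetraploid against diploid these were 16, 13 and 0 against 0, 18 and 0, with at least 13 lists in 7 splits, and for triploid against tetraploid 589, 15 and 0 against 10, 23 and 3, with at least 15 lists in 6 splits. Over 100 splits of all 9 arrays, the real one included, the real split called the most genes in 2 tests. It called 691 for triploid clones against the others, where the other splits gave at most 473. For any difference among ploidies it called 518, where the others gave at most 150. The share of splits with as many calls was thus under 0.05 in both. For the lists of triploid against the others, 60 splits gave at least 13, and the highest gave 23. The count of lists thus did not set the real split apart here. Nor did it for tetraploid against diploid or triploid against tetraploid clones. Such splits take the clones as exchangeable and cannot separate ploidy from clone history.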
